A study of Homo sapiens with 8 samples.

How the data were processed

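Gene expression was measured on microarrays in 2 human Ewing sarcoma cell lines, A673 and SK-ES1. Cells of each line carried either a short hairpin RNA against RING1B (shRING1B) or a control hairpin against GFP (shGFP). The series holds 4 groups of 2 arrays, 8 arrays in all, and each array was put in its group by the cell line and treatment in its labels. Replicate numbers were given in accession order and only name an array. Per the labels' protocols, RNA was extracted with a Qiagen protocol, and 30 ng of total RNA per sample was labelled with an Affymetrix whole-transcript kit.

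The deposited values are log2 expression values per probe set, with 1 value for each of 48144 probe sets on each array. Per the submitters' processing notes, RMA and limma were used, without stated versions. RMA corrects the background of each array, normalizes the arrays to a common distribution by quantiles and summarises the probes of a probe set. Its quantile step makes arrays alike in distribution, so a change shared by most genes would not show in these values. The array version and the annotation used upstream were not given in the sources used here. No scanner files were used here, so signal over background was not measured per probe set, and the number of arrays limits the precision. No genome build was given in the sources used here, and no coordinates are printed.

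Probe sets were named through a table of the platform's gene annotation. Of the 48144 probe sets, 16098 (33.4%) had 1 gene symbol, 0 had several and 32046 were unnamed here, which does not mean that they measure no gene. Each gene was represented by its probe set with the highest mean over the 8 arrays, which gave 14884 genes, of which 11915 are protein-coding by RefSeq's annotation of GRCh38.p14. That annotation was used only for gene names, gene types and the order of neighbouring genes. For 779 genes more than 1 probe set was named. The level of RNF2, the gene of RING1B, was not analysed here, so the labels were not checked against the targeted gene. No column of per-sample values was left unused.

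A linear model with 4 group means was fitted to the log2 values of all 8 arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 installed beside it. The model has 4 residual degrees of freedom, and the empirical Bayes step added 6 prior degrees of freedom. All 4 groups share the estimate of spread because a fit of 2 groups of 2 arrays has few degrees of freedom. The contrasts were shRING1B minus shGFP in A673, the same in SK-ES1, the mean of these 2 effects, their difference (SK-ES1 minus A673), and SK-ES1 minus A673 under shGFP. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 14884 genes of a contrast. A gene is called when its adjusted p is under 0.05, with no minimum fold. Every adjusted p for a gene in the text comes from limma. Values written with ± are means and standard deviations over the 2 arrays of a group, or over the genes of a list where that is said. Standard errors of log2 changes come from the model.

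Gene lists were tested with camera at a preset correlation between genes of 0.01, and the p-values of the 21 lists with at least 3 measured members were adjusted together within a contrast. Beside it, camera with a correlation estimated per list and fry were run. Camera asks whether a list moves relative to other genes, and fry asks whether its genes move, on balance, one way. The lists cover targets activated or repressed by EWSR1-FLI1, components of Polycomb repressive complexes 1 and 2 (PRC1 and PRC2), HOX genes and other developmental transcription factors, responses to NF-kB, interferon, TGF-beta, p53, hypoxia and unfolded protein, DNA replication, mitosis, cholesterol synthesis, extracellular matrix, ribosomal proteins, and neuronal, endothelial, immune and epithelial genes. A further list was not analysed here. For the lists described in a comparison, counts of members past the threshold are given over all genes and adjusted over the list alone.

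The lists, the tests, the rule for named genes and most alternative settings were fixed before the data were examined. The rule names up to 10 rises and 10 falls with the largest change among called protein-coding genes whose shRING1B arrays all lie on 1 side of the shGFP arrays, in both lines for the mean effect. Where fewer than 5 genes were called in a direction, it names the 5 with the smallest p. It also names genes called in both lines, 5 genes per direction for the difference between lines, 10 per direction for the baseline, and up to 4 members of each list with the smallest p. Genes of the neighbour runs and zinc-finger families were singled out after their values were seen.

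The order of genes along chromosomes was examined after the data were seen. This used 5954 protein-coding genes with a mean log2 signal above 5.78. The running median of the log2 change over 25 neighbouring genes was compared with the extremes of 1000 shuffles of gene order. The 95% point of the shuffled maxima was the threshold, taken for each line by itself. Runs separated by at most 12 genes were merged.

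The model was tested on simulated data made from the real means and from spreads moderated by its own empirical Bayes step. Such spreads are more alike between genes than the observed ones, which favours the model. For the A673 comparison over 14884 genes, with 100 genes changed at each size, it recovered 51% of genes changed 1.5-fold and 99% of those changed 2-fold, and called 12 unchanged genes. For the SK-ES1 comparison it called 0 unchanged genes when none was changed. Among 20 simulated lists of 20 genes with a log2 shift of 0.5 in the first, camera called 1 list, the shifted one, and 0 others. The noise was drawn independently for each gene, so false calls of lists whose genes vary together were not tested.

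Alternatives tried were a filter on low signal, quantile normalization repeated, array medians set equal, a trended and robust variance model, array weights, the mean of a gene's probe sets, all probe sets tested, a minimum fold, an unadjusted threshold, fits of 4 arrays, an additive model, and each array left out in turn. Cyclic loess normalization and a fit without the genes lying in the neighbour runs were added after seeing the data.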

Results

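Ewing sarcoma is a tumour of bone and soft tissue, mostly of young people, driven by a fusion of EWSR1 with an ETS transcription factor, most often FLI1. RING1B, encoded by RNF2, is a ubiquitin ligase of PRC1, which marks histones and is best known for keeping developmental genes silent. Gene expression was measured in A673 and SK-ES1, 2 established Ewing sarcoma lines, with a short hairpin RNA against RING1B or a control hairpin against GFP. Each of the 4 groups had 2 arrays, and the array medians of the deposited log2 values lay between 4.01 and 4.1. The series title ties RING1B to EWSR1-FLI1 and chromatin, and the comparisons ask which transcripts changed when RING1B was targeted. The level of RNF2 itself was not analysed here, so unequal depletion cannot be told apart from an unequal response of the lines. Nothing in the labels says that the replicate arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

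The line was the main source of variation. The first principal component held 78.1% of the variance and separated A673 from SK-ES1, and the second held 8% and separated the A673 shRING1B arrays from the A673 shGFP arrays. Arrays of the same group correlated at 0.9911 to 0.9937 across the 14884 genes. Between hairpins the correlation was 0.9827 to 0.9875 in A673 and 0.9909 to 0.9918 in SK-ES1. No 2 arrays were identical.

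In A673, genes that fell under the RING1B hairpin outnumbered those that rose, and the larger changes were almost all falls. The zinc-finger genes ZNF208, ZNF681 and ZNF429 fell by 2.42, 2.4 and 2.21 on the log2 scale. NEUROD6, a neuronal transcription factor, fell by 2.03 and the cardiac T-box factor TBX20 by 1.88. The strongest rises were smaller and included NPR3, the clearance receptor of natriuretic peptides, the stress enzyme HMOX1 and the muscle precursor factor PAX7. Of 14884 genes, limma called 557, of which 105 rose and 452 (81.1%) fell. At 2-fold or more, 2 rose and 122 fell. At an unadjusted p under 0.05, 2819 genes passed, where chance gives 744, and these were more evenly split (1317 higher, 1502 lower). The count of 557 was 317 without A673 shGFP replicate 1, 101 without A673 shGFP replicate 2, 241 without A673 shRING1B replicate 1 and 321 without A673 shRING1B replicate 2. It was 213 in a fit of the 4 A673 arrays alone and 1052 with a trended, robust variance model.

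Among the A673 rises, NPR3 went from 4.28 ± 0.288 to 5.52 ± 0.287 (SD, n = 2), a log2 change of 1.24 with a standard error of 0.175 (limma adjusted p = 0.00499). QRFPR, a neuropeptide receptor, rose by 0.98 (adjusted p = 0.00577) and CAPN6, a calpain-family protein, by 0.97 (adjusted p = 0.00284). DHRS3, a retinal reductase, rose by 0.95 and PAX7 by 0.84 (adjusted p = 0.0126). CRIM1, MCEMP1, TMC5 and OCIAD2 rose by 0.88, 0.83, 0.79 and 0.78. HMOX1 rose by 0.99 (adjusted p = 0.0384). Among the rises named here, CAPN6 and DHRS3 stayed called with each array left out. The others each lost the call without A673 shGFP replicate 2, where NPR3 had 0.0624, QRFPR 0.0728, HMOX1 0.191, PAX7 0.148, TMC5 0.064, MCEMP1 0.117, CRIM1 0.189 and OCIAD2 0.193. Some lost it without another array too. Without A673 shGFP replicate 1 these were HMOX1 (0.156), MCEMP1 (0.106), CRIM1 (0.0705) and OCIAD2 (0.0696), and without A673 shRING1B replicate 2 HMOX1 (0.122), CRIM1 (0.104), MCEMP1 (0.0989) and OCIAD2 (0.0984). Without A673 shRING1B replicate 1 they were PAX7 (0.0618) and OCIAD2 (0.0615), and without either SK-ES1 shRING1B array HMOX1 (0.0695).

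Among the falls, ZNF208 went from 6.28 ± 0.0897 to 3.85 ± 0.0617 (adjusted p = 0.000222) and NEUROD6 from 9.23 ± 0.000651 to 7.20 ± 0.086 (adjusted p = 0.00135). TBX20 went from 8.57 ± 0.491 to 6.69 ± 0.0493 (adjusted p = 0.00135). DSG2, a desmosomal cadherin, went from 6.90 ± 0.24 to 4.95 ± 0.0196 (adjusted p = 0.000295). LRCH2 fell by 2.01, the stress-response gene SESN3 by 1.93 and the kinesin KIF21A by 1.89. ZNF675 fell by 1.79 (adjusted p = 0.0114). Of these 10 named falls, ZNF681 and ZNF675 lost their call when A673 shGFP replicate 2 was left out, with an adjusted p of 0.1 and 0.101, and ZNF675 also without A673 shGFP replicate 1 (0.0526) or A673 shRING1B replicate 1 (0.0653).

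**Figure D1:**
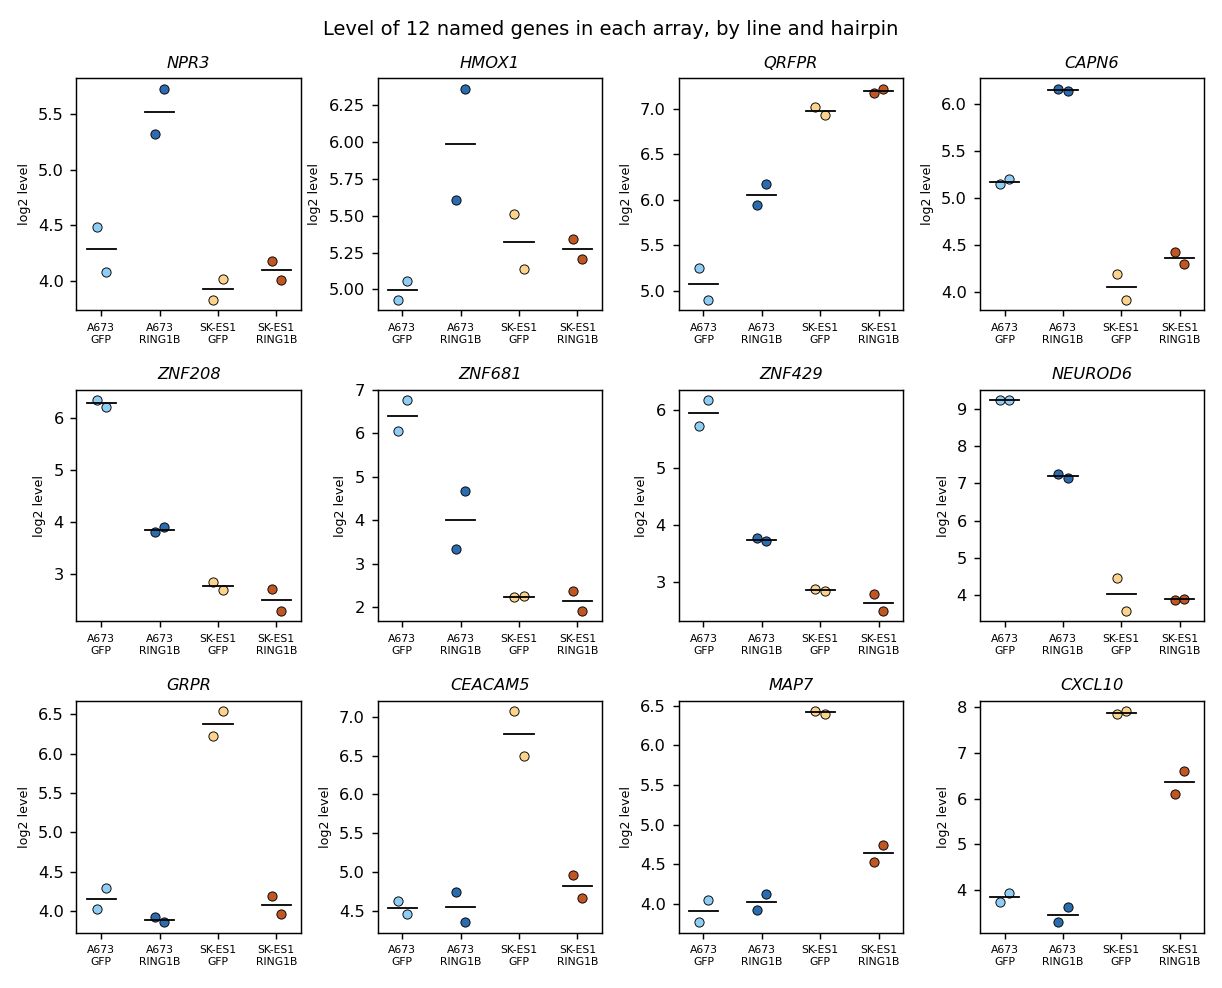
Log2 expression of 12 named genes (NPR3, HMOX1, QRFPR, CAPN6, ZNF208, ZNF681, ZNF429, NEUROD6, GRPR, CEACAM5, MAP7 and CXCL10) in each of the 8 arrays, grouped by line and hairpin. Points are arrays and lines are means of 2, with ZNF208 at 6.28 under shGFP and 3.85 under shRING1B in A673, and GRPR at 6.38 and 4.07 in SK-ES1.

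Many of the zinc-finger falls lay in 2 stretches of neighbouring genes. These stretches were singled out after their values were seen, and their genes belong to a large family of DNA-binding repressors. On chromosome 19, 29 ZNF genes were measured between ZNF506 and ZNF254, and 24 of them lay above the array median in A673 shGFP. Of those 24, all had a log2 change below 0 in A673, with a median of -0.98 and a range of -2.42 to -0.171. Choosing genes by their shGFP level favours falls, and over all 29 the median was -0.804. Of the 29, 11 were called. On chromosome 7, from ZNF736 to ZNF92, 6 of 7 ZNF genes fell and the median was -0.946, with ZNF117 at -1.65 and ZNF138 at -1.42. Among the other 431 ZNF genes 17 fell and 3 rose, and the median change of the 384 above the array median was -0.0398. In SK-ES1 no member was among the 10 genes called, and the median was -0.133 over the 29 genes and -0.181 over the 7. Under shGFP the median level was 3.65 in SK-ES1 and 6.11 in A673 for the chromosome 19 genes, and 4.27 and 6.81 for the chromosome 7 genes, against a median of all probe sets of 4.06. In SK-ES1 shGFP 8 of the 29 and 4 of the 7 lay above that median. The median change of these was -0.293, with 7 of 8 below 0, and -0.247, with 4 of 4 below 0. It was -0.0438 over the 357 other ZNF genes above it. These genes were kept by their level in the same shGFP arrays that the change is measured from, which favours falls. Without that choice the medians were the -0.133 and -0.181 given above. ZNF208 stood at 2.78 ± 0.11 in SK-ES1 shGFP, while ZNF138 stood at 6.07 and ZNF431 at 5.75. The log2 changes of ZNF138 and ZNF431 in SK-ES1 were -0.314 and -0.3, which limma did not call. The directions in A673 were the same under each normalization tried. Members of this family share sequence, so single-gene values are uncertain.

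Other falls in A673 lay among genes next to each other on a chromosome. Along 5954 expressed genes in chromosomal order, the running median over 25 neighbours was set against a threshold from shuffled gene order. It passed downwards in 17 runs and upwards in 2 in A673, against 2 and 0 in SK-ES1. Each line had its own threshold, 0.23 in A673 and 0.136 in SK-ES1. The running median in SK-ES1 lay between -0.15 and 0.123, so no SK-ES1 run would pass the A673 threshold. The medians of the 17 lower runs ranged from -0.557 to -0.0964, 12 of them above -0.35, and 230 of their 264 genes lay below 0. In the run with the weakest median, from MCM3 to GSTA4, 2 of 4 genes lay below 0, so these 4 were not lower together. The run on chromosome 7 from NUP42 to MPLKIP held 28 genes, of which 27 lay below 0 with a median of -0.557 and 12 fell, among them NEUROD6 and TBX20. On chromosome 1 the runs from EVI5 to NTNG1 and from DRAM2 to GDAP2 had medians of -0.51 and -0.42. The run on chromosome 8 from ZBTB10 to SQLE held 64 genes with a median of -0.334, and 15 fell. In SK-ES1 the medians of these runs were -0.0511, -0.0408, -0.02 and -0.0161, and the last 2 changed sign with quantile normalization repeated. Of the 452 falls, 87 lay among the 619 tested genes between the ends of the lower runs, which were found from the same log2 changes, and the median change of the 619 was -0.173. Without these genes, an alternative added after seeing the data, 406 genes were called in A673, 78 higher and 328 lower.

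**Figure D2:**
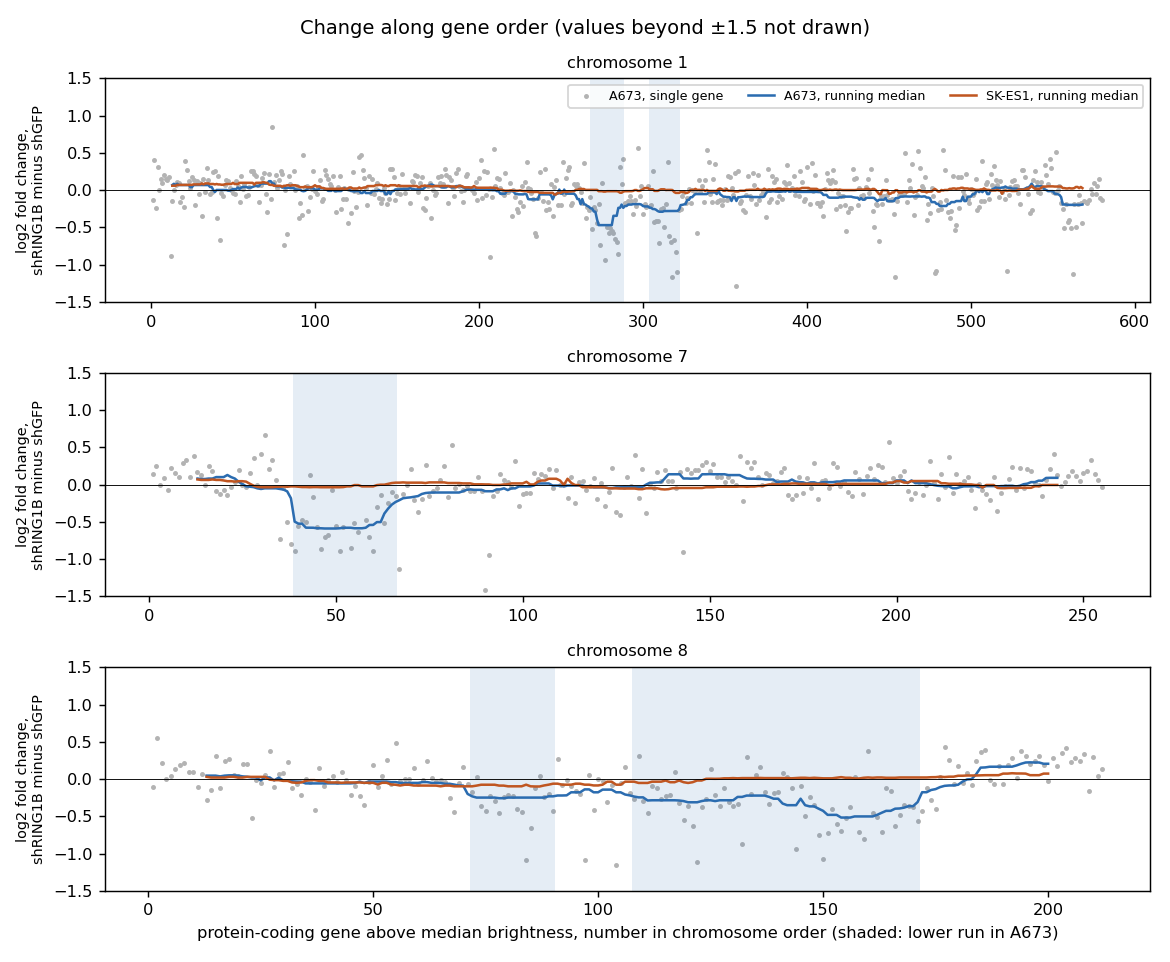
Log2 change (shRING1B minus shGFP) along genes in chromosomal order on chromosomes 1, 7 and 8, with single A673 genes as dots and the running median over 25 genes for each line as curves. Shaded stretches are the lower runs in A673, such as NUP42 to MPLKIP with a median of -0.557. The vertical axis is limited to 1.5 on either side of 0.

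Of the fixed gene groups in A673, developmental transcription factors outside the HOX clusters were shifted down. Of 96 measured, 9 fell and 1 rose, with 13 and 3 when adjusted over the list alone, and the mean change was -0.138 ± 0.375 (SD over genes). TBX5 fell by 1.52, TBX20 by 1.88 and the neural crest factor TFAP2B by 1.09, while PAX7 rose by 0.84. Camera's adjusted p was 0.0194, and the adjusted p was 0.565 with an estimated correlation, 0.104 with quantile normalization repeated, 0.0535 with cyclic loess and 0.0649 without A673 shRING1B replicate 2. TBX20, EVX1, NKX2-5 and SOX17 lie within lower runs, and without the genes of the runs the adjusted p was 0.00795. The DNA replication list was shifted up by 0.135 ± 0.352, with 21 of 24 members above 0 (adjusted p = 0.0194, and adjusted p = 0.565 with an estimated correlation). CDT1, a replication licensing factor, rose by 0.53 and CCNE1, cyclin E1, fell by 1.24, 1 gene called each way, and 4 rose and 2 fell adjusted over the list alone. CDT1 lost its call in 11 of 18 alternatives, with an adjusted p of up to 0.332, and is the called gene of the 3 in the higher run from CDT1 to GALNS. The replication call was lost without A673 shGFP replicate 2 (0.202), A673 shRING1B replicate 1 (0.0656) or A673 shRING1B replicate 2 (0.0649).

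The other 19 lists tested in A673 had a camera adjusted p of 0.208 or more. Among 24 EWSR1-FLI1 activated targets, PAX7 rose and the receptor kinase KIT fell by 0.57, and the mean change was 0.0962 (adjusted p = 0.241). Adjusted over the list alone, 5 rose and 3 fell. None of 10 repressed targets was called by limma over all genes or adjusted over the list alone, with a mean of 0.139 (adjusted p = 0.418) and CCN2 at 0.768 (adjusted p = 0.0865). Among 21 PRC1 components SCML2 fell by 0.56, and among 11 PRC2 components MTF2 fell by 0.52, and both lie in lower runs (list adjusted p = 0.842 and 0.241). Of 27 HOX genes, 20 had values above 0, while HOXA2, HOXB8 and HOXB9 fell by 0.96, 0.70 and 0.56 (list adjusted p = 0.361), and HOXA2 lies in the chromosome 7 run. The chemokine CCL2 fell by 0.88 among 17 NF-kB genes (list adjusted p = 0.208). The p53 target RRM2B fell by 0.94 and the cholesterol gene SQLE by 0.56, both in the chromosome 8 run (list adjusted p = 0.241 and 0.292). DCX and NCAM1 fell by 0.78 and 0.65 among 14 neuronal genes (0.241). IFIH1 and IFI44L fell by 0.61 and 0.77 among 22 interferon genes (0.422). PGM1 fell by 0.57 in the hypoxia list (0.241), RPL31 by 0.70 among ribosomal protein genes (0.418), and KRT18 rose by 0.59 among epithelial markers (0.241). No member of the mitosis (0.375), unfolded protein (0.255), extracellular matrix (0.241), TGF-beta (0.241), endothelial (0.842) or immune (0.361) lists was called over all genes, and adjusted over the list alone 2 TGF-beta genes and 1 endothelial gene rose and 2 unfolded protein genes fell. For the lists with a called member, the counts adjusted over the list alone were 2 rises and 1 fall for PRC1, 2 falls for PRC2, 2 rises and 3 falls for HOX, 4 falls for NF-kB, 2 for p53, 3 for cholesterol, 2 for neuronal and 3 for interferon genes, 1 rise and 2 falls for hypoxia, 1 fall for ribosomal and 1 rise for epithelial genes. Most of these single-gene calls were lost under several alternatives. KRT18 lost its call in 12 of 18 (adjusted p up to 0.345), IFI44L in 11 of 18 (0.199), SCML2 in 11 of 17 (0.289), MTF2 in 10 of 17 (0.245), PGM1 in 9 of 18 (0.294) and IFIH1 in 8 of 18 (0.224). SQLE lost it in 7 of 17 (0.218), RPL31 in 7 of 18 (0.178), HOXB9 and KIT in 6 of 18 (0.239 and 0.224), HOXB8 in 5 of 18 (0.208), NCAM1 in 4 of 18 (0.165), CCL2 and HOXA2 in 2 (0.13 and 0.187), and DCX and RRM2B in 1 (0.126 and 0.0816). The highest of these p-values came without A673 shGFP replicate 2, or without A673 shGFP replicate 1 for IFI44L and RPL31.

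**Figure D3:**
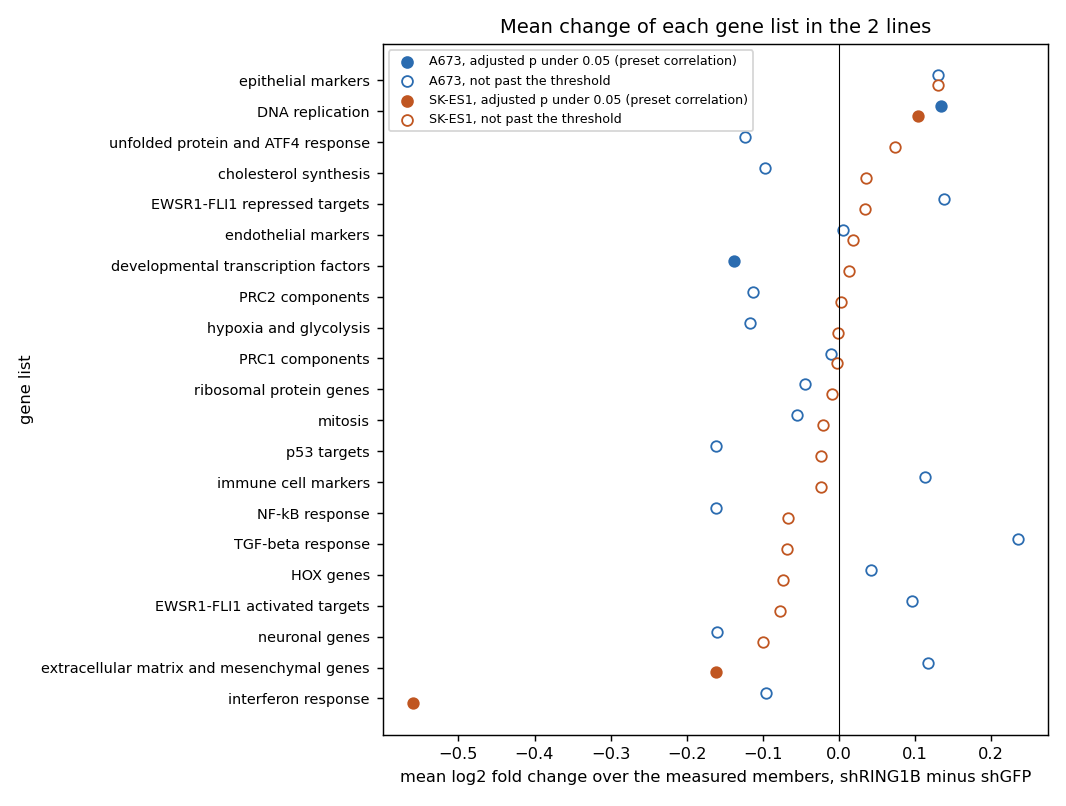
Mean log2 change (shRING1B minus shGFP) of each fixed gene list in A673 and SK-ES1. Filled points have a camera adjusted p under 0.05, such as interferon genes at -0.56 in SK-ES1 and developmental transcription factors at -0.138 in A673.

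In SK-ES1, fewer genes were called, and each of them fell. GRPR, the receptor of gastrin-releasing peptide, went from 6.38 ± 0.226 to 4.07 ± 0.161 (SD, n = 2), a log2 change of -2.30 with a standard error of 0.15 (limma adjusted p = 0.000411). CEACAM5, a cell adhesion antigen, fell by 1.96 (adjusted p = 0.0078) and MAP7, a microtubule-binding protein, by 1.78 (adjusted p = 0.00111). CXCL10, BST2 and SP100, all known as interferon-induced, fell by 1.53, 1.29 and 1.07. LGR5, a stem-cell receptor of R-spondins, fell by 1.15, the neurosecretory genes SYT4 and SCG2 by 1.12 and 1.05, and the kinase NEK7 by 0.91. These are the 10 genes that limma called, with 0 higher, while 1095 genes passed an unadjusted p under 0.05 (481 higher, 614 lower), where chance gives 744. Values for the rises with the smallest p were 1.15 for ACTL8 (adjusted p = 0.0618) and 0.88 for IGFBP3 (0.07), with RGS9BP at 0.69 (0.114), CCL27 at 0.58 (0.153) and FBXO24 at 0.58 (0.224). The count of 10 was 2 without SK-ES1 shGFP replicate 1, 4 without SK-ES1 shGFP replicate 2, 3 without SK-ES1 shRING1B replicate 1 and 3 without SK-ES1 shRING1B replicate 2. GRPR and MAP7 stayed called with each array left out, and the highest adjusted p over all alternatives was 0.133 for CEACAM5 and LGR5, 0.16 for CXCL10, 0.1 for BST2, 0.246 for SYT4, 0.255 for SP100, 0.349 for SCG2 and 0.296 for NEK7.

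The interferon response list moved down together in SK-ES1. Of 22 genes, 19 lay below 0, with a mean change of -0.56 ± 0.415 (SD over genes) and a camera adjusted p of 3.66e-20 (adjusted p = 0.00982 with an estimated correlation, and 0.000796 by fry). BST2 was the member called over all genes, and 13 fell when adjusted over the list alone. IFI44L had a log2 change of -1.23 (adjusted p = 0.0525), IFIT1 of -1.07 (0.07), IFI44 of -0.869 (0.0525) and RIGI of -0.855 (0.0692). The mean level of the list was 6.21 and 6.27 in the SK-ES1 shGFP arrays and 5.71 and 5.66 in the shRING1B arrays. In A673 it was 4.74 and 4.73 under shGFP and 4.64 and 4.63 under shRING1B.

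**Figure D4:**
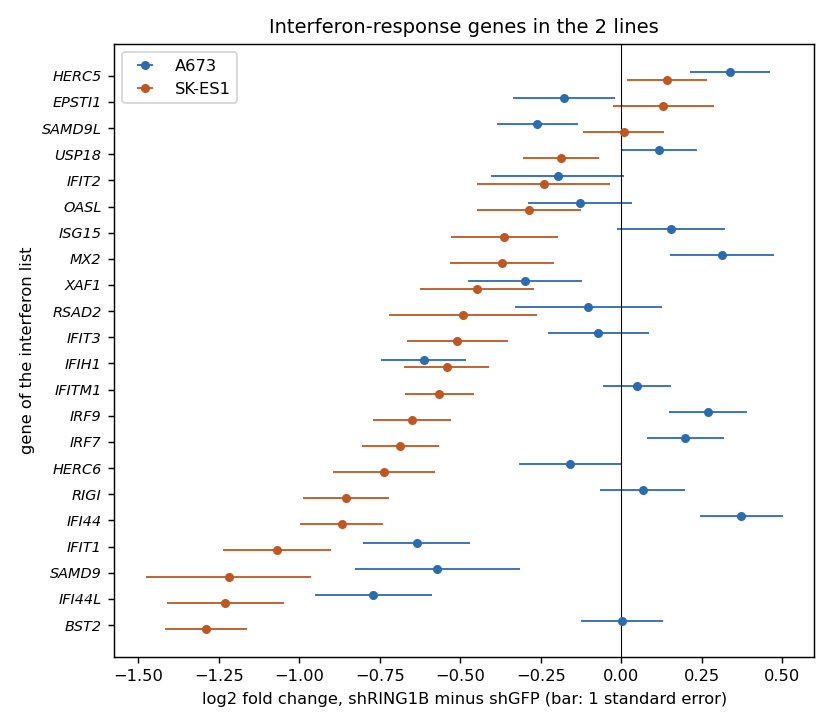
Log2 change (shRING1B minus shGFP) of the 22 measured interferon response genes in A673 and SK-ES1, with bars of 1 standard error. In SK-ES1, 19 of the 22 genes lie below 0, with BST2 at -1.29, and in A673 12 do.

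Other list shifts in SK-ES1 were small. DNA replication genes had a mean change of 0.104 ± 0.127 with 22 of 24 above 0 and 0 called by limma, over all genes or over the list alone (camera adjusted p = 0.00691, and adjusted p = 0.748 with an estimated correlation). That call was lost without SK-ES1 shGFP replicate 2 (0.374) or SK-ES1 shRING1B replicate 2 (0.0889). Extracellular matrix and mesenchymal genes had a mean of -0.162 ± 0.33 with 11 of 14 below 0 (adjusted p = 0.0153, and adjusted p = 0.469 with an estimated correlation), and 1 rose and 2 fell when adjusted over the list alone. TWIST1 stood at -0.665 (adjusted p = 0.152) and FN1 at 0.547 (0.463). That call was lost without SK-ES1 shGFP replicate 2 (0.407) or SK-ES1 shRING1B replicate 1 (0.0603). SCG2 was the called member of the neuronal list, over all genes and adjusted over the list alone (list adjusted p = 0.539). The remaining lists had an adjusted p between 0.0638, for epithelial markers with a mean of 0.131, and 0.89, with 0 members called over all genes by limma, and adjusted over the list alone 1 repressed target rose and 1 HOX and 1 NF-kB gene fell. Mean changes were -0.0772 for EWSR1-FLI1 activated targets, 0.0348 for repressed targets, -0.0734 for HOX genes, 0.0141 for developmental factors, -0.0016 for PRC1 and 0.00241 for PRC2 components. The mean and the median differed in sign for the repressed targets and for the PRC1, p53, hypoxia, immune and ribosomal protein lists. The ribosomal protein list, at 0.89, was called up without SK-ES1 shRING1B replicate 1 (0.00636) and down without SK-ES1 shRING1B replicate 2 (0.000951).

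The measured log2 changes of the lines had little in common gene by gene. Across 14884 genes the log2 changes correlated at r = 0.0416 (Spearman's rho = 0.0252), where genes are not independent replicates and the comparisons share no arrays. NEK7, a kinase of the inflammasome, was the only gene called in both lines, falling by 1.09 in A673 and by 0.91 in SK-ES1, against 0.304 shared falls for independent lists. Its SK-ES1 call was lost with any 1 of the 8 arrays left out (adjusted p of 0.0516 to 0.296). No gene was called in both lines in opposite directions, with 0.0705 for independent lists. Of the 452 A673 falls, 269 (59.5%) lay below 0 in SK-ES1, compared with 51% of all genes, and 47 of the 105 A673 rises (44.8%) lay above 0. The spread of log2 changes over genes was 0.277 (SD) in A673 and 0.183 in SK-ES1, with a median standard error of 0.134 in each. Noise therefore lowers the correlation, and no rise could be shared because 0 rises were called in SK-ES1. The model gives a gene the same standard error in both lines. Replicate arrays differed by an SD over genes of 0.211 and 0.254 in the A673 groups and 0.227 in each SK-ES1 group. Noise was therefore not clearly higher in SK-ES1, where the changes spread less. Small changes there that miss the threshold cannot be told apart from no change, and the test of the difference itself is given below.

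**Figure D5:**
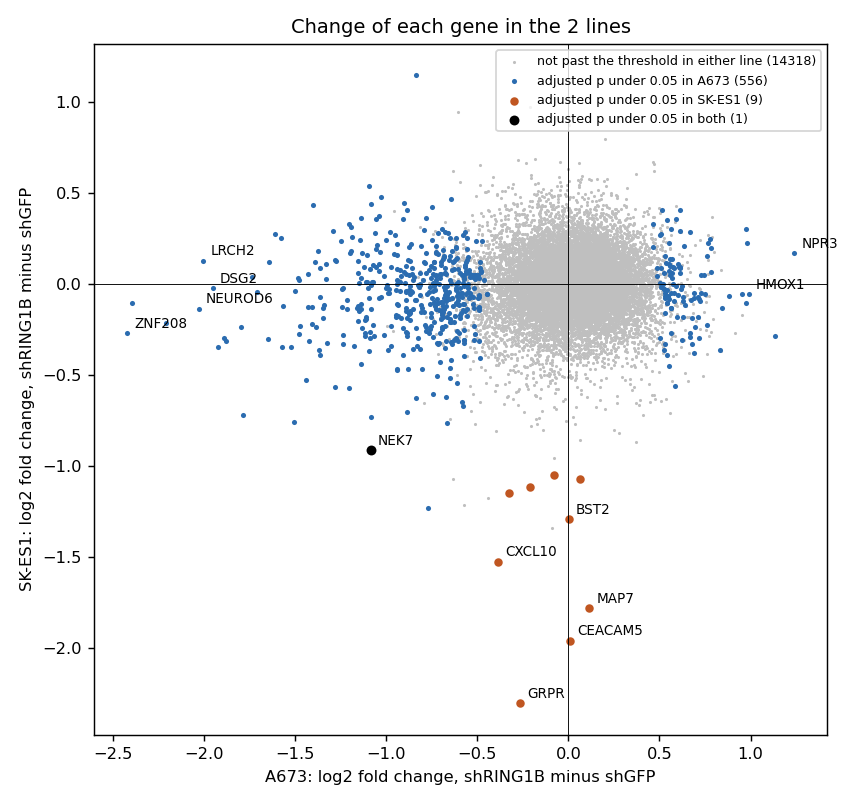
Log2 change (shRING1B minus shGFP) in A673 on the horizontal axis and SK-ES1 on the vertical axis for 14884 genes, coloured by the line in which limma called them. The cloud has a correlation of 0.0416, and NEK7 is the gene called in both lines.

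For the effect averaged over both lines, TMEM88, an inhibitor of Wnt signalling, fell by 1.13 (limma adjusted p = 0.00067), with a log2 change of -1.51 in A673 and -0.755 in SK-ES1. IFI44L and NEK7 each fell by 0.999, the growth suppressor NDN by 0.96 and the neuronal filament gene PRPH by 0.98. GRPR fell by 1.28, ZNF429 by 1.21, SESN3 by 1.14, TBX20 by 1.10 and KIF21A by 1.09, each called in 1 of the lines. CAPN6 rose by 0.64 (adjusted p = 0.00831) and QRFPR by 0.60, and FJX1, ANKRD52, TMC5, CCL8, CYYR1, AVP, FAM241A and PKP1 rose by 0.51 to 0.45. In all 202 genes were called, 17 higher and 185 lower. The interferon list had a mean of -0.328 ± 0.307 with 21 of 22 genes below 0 (camera adjusted p = 2.05e-09, and adjusted p = 0.0431 with an estimated correlation). Of its members IFI44L, IFIT1, BST2 and IFIH1 were among 5 that fell, and 12 fell and 1 rose adjusted over the list alone. IFIH1 lost its call in 7 of 18 alternatives (adjusted p up to 0.0901), BST2 in 2 (0.304) and IFIT1 in 1 (0.0659). DNA replication genes had a mean of 0.12 ± 0.226 with 22 of 24 above 0 (adjusted p = 0.000203, and adjusted p = 0.57 with an estimated correlation). Adjusted over the list alone 5 rose and 1 fell, and CCNE1, the member called over all genes, fell by 0.78. The count of 202 was 8 in an additive model of line and hairpin, 481 with a trended, robust variance model and 130 without the genes of the lower runs. It was 71 without A673 shGFP replicate 2, 119 without A673 shRING1B replicate 1, 89 without SK-ES1 shGFP replicate 1, 96 without SK-ES1 shGFP replicate 2, 87 without SK-ES1 shRING1B replicate 1 and 51 without SK-ES1 shRING1B replicate 2. Of the 10 named rises, only CAPN6 stayed called with each array left out, and of the named falls SESN3 and TBX20 lost their call without SK-ES1 shRING1B replicate 2.

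The test of the difference between lines found 117 genes, of which 93 had a more positive change in SK-ES1 and 24 a more negative one. The differences (SK-ES1 minus A673) were 2.15 for ZNF208, 2.13 for LRCH2, 1.99 for ZNF429, 1.93 for DSG2 and 1.99 for ACTL8, which fell by 0.84 in A673. They were -2.04 for GRPR, -1.97 for CEACAM5, -1.90 for MAP7, -1.29 for BST2 and -1.24 for IFI44. Most of these genes were low in the line without a call, where a fall would be hard to see. GRPR, MAP7 and BST2 stood at 4.15, 3.91 and 3.85 in A673 shGFP, near the median of all probe sets (4.06), and ZNF208, ZNF429, DSG2 and LRCH2 at 2.78, 2.86, 3.15 and 3.32 in SK-ES1 shGFP, below it. KIF21A was different, at 7.39 in A673 shGFP and 7.4 in SK-ES1 shGFP, with a difference of 1.60 (adjusted p = 0.013). The interferon list differed between lines (mean -0.464 ± 0.431, camera adjusted p = 1.11e-06, and adjusted p = 0.0821 with an estimated correlation), with BST2, IFI44, IRF9 and IRF7 called and 7 genes more negative adjusted over the list alone. Developmental factors differed the other way (mean 0.152, adjusted p = 0.0102, and adjusted p = 0.291 with an estimated correlation, 0.0536 with quantile normalization repeated and 0.0533 with cyclic loess), with TBX20 and TBX5 called, and 12 more positive and 1 more negative adjusted over the list alone. Extracellular matrix genes had a mean of -0.278 (adjusted p = 0.0292, and adjusted p = 0.295 with an estimated correlation) with TWIST1 at -1.05, the member called over all genes and over the list alone, and lost the call without A673 shGFP replicate 1 (0.0898), A673 shRING1B replicate 2 (0.18) or SK-ES1 shGFP replicate 2 (0.156). Of these list members IRF7 lost its call in 11 of 17 alternatives (adjusted p up to 0.214), IRF9 in 10 of 17 (0.164), TBX20 in 10 of 16 (0.188), TBX5 in 9 of 17 (0.173) and TWIST1 in 8 of 17 (0.152). The count of 117 depended on every array. It was 72, 9, 67 and 66 without A673 shGFP replicates 1 and 2 and A673 shRING1B replicates 1 and 2, 21 and 27 without SK-ES1 shGFP replicates 1 and 2, 0 by limma without SK-ES1 shRING1B replicate 1 (1833 at an unadjusted p under 0.05) and 1 without SK-ES1 shRING1B replicate 2.

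Under the control hairpin the lines differed in 4572 genes, 2043 higher and 2529 lower in SK-ES1, of which 440 and 750 by 2-fold or more. Line and anything processed with it could not be told apart. Interferon genes were higher in SK-ES1, with 18 of 22 called higher and a mean difference of 1.51 ± 1.13 (camera adjusted p = 4.18e-12, and adjusted p = 0.0266 with an estimated correlation), including IFIH1 at 3.82 and BST2 at 2.99. The cancer-testis gene SAGE1 was higher by 5.92 and the meiotic cohesin SMC1B by 5.29. MBD3L5, MBD3L3 and MBD3L2 were higher by 7.10, 7.06 and 6.88, but these near-identical paralogs are uncertain one by one. FN1, fibronectin, was lower in SK-ES1 with a difference of -6.41 (11.6 against 5.14), F2RL2 with -6.87, the neural factor OTX2 with -5.65 and NEUROD6 with -5.20. Of 10 EWSR1-FLI1 repressed targets, 8 were lower in SK-ES1, with DKK1 at -4.48 and TNC at -4.07 (mean -1.70 ± 1.55, adjusted p = 1.81e-05, and adjusted p = 0.469 with an estimated correlation). Extracellular matrix genes had 3 higher and 7 lower (mean -1.02, adjusted p = 0.0213, and adjusted p = 0.469 with an estimated correlation). Mitotic genes were lower, with FOXM1 at -0.856 and 8 of 23 called (adjusted p = 0.0049, and adjusted p = 0.671 with an estimated correlation). Ribosomal protein genes had a mean of 0.205 with 7 called higher (adjusted p = 0.0256, and adjusted p = 0.763 with an estimated correlation), a call lost without SK-ES1 shGFP replicate 2 (0.135). Adjusted over the list alone, 18 interferon genes were higher and 1 lower, 9 repressed targets and 8 mitotic genes were lower, 3 extracellular matrix genes were higher and 8 lower, and 2 ribosomal protein genes were higher.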

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

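The tests of explanations in this part were chosen after the results were seen, except the count of other splits of the arrays, whose limit to splits balanced over the lines was also set later.

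The change between hairpins differed between the lines for 117 genes, by limma's test of the difference itself (SK-ES1 minus A673). Because the level of RNF2 was not analysed here, unequal depletion cannot be told apart from an unequal response. The log2 difference was 2.15 for ZNF208, 2.13 for LRCH2, 1.99 for ZNF429 and for ACTL8, 1.93 for DSG2, 1.89 for NEUROD6, 1.6 for KIF21A, 1.57 for TBX20 and 1.23 for NDN. It was -2.04 for GRPR, -1.97 for CEACAM5, -1.9 for MAP7, -1.29 for BST2, -1.24 for IFI44, -1.19 for MCEMP1, -1.14 for SP100 and -1.01 for DHRS3. In the line without a call some of these genes stood near or below the median of all probe sets (4.06), where a fall would be hard to see: ZNF208, ZNF429, DSG2, LRCH2 and NEUROD6 at 2.78, 2.86, 3.15, 3.32 and 4.03 in SK-ES1 shGFP, and SP100, BST2, MAP7 and GRPR at 3.83, 3.85, 3.91 and 4.15 in A673 shGFP. KIF21A, TBX20 and NDN stood at 7.4, 7.53 and 7.71 in SK-ES1 shGFP. Among the gene lists the interferon response (camera adjusted p = 1.11e-06), developmental transcription factors (0.0102) and extracellular matrix genes (0.0292) differed, and none of the 3 kept its call with an estimated correlation (0.0821, 0.291 and 0.295). The count of 117 fell to 0 by limma without SK-ES1 shRING1B replicate 1, where 1833 genes passed an unadjusted p under 0.05. It was 1 without SK-ES1 shRING1B replicate 2, 21 and 27 without SK-ES1 shGFP replicates 1 and 2, 72 and 9 without A673 shGFP replicates 1 and 2, and 67 and 66 without A673 shRING1B replicates 1 and 2.

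Probe sets without a gene name here, which enter no comparison above, also changed. Of 32046, limma called 364 in A673, 54 higher and 310 lower, when all probe sets were tested together. One of these had a log2 change of -2.68 (limma adjusted p = 0.000334), a larger fall than that of ZNF208 (-2.42). In SK-ES1 limma called 0. At an unadjusted p under 0.05 there were 4282 in A673 and 2106 in SK-ES1, a threshold that many of the 32046 would pass by chance.

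Runs of neighbouring genes were lower in A673 shRING1B. Runs were found on every other gene and measured on the 62 genes between them, on chromosomes 1, 2, 7 and 8. The median log2 change of the 62 was -0.516, with 90.3% below 0 against 44.4% of genes elsewhere, and a median of -0.0476 in SK-ES1. On chromosome 2 there were 4 such genes, with a median of -0.182 in A673. Lower runs on other chromosomes gave no such genes, so this check does not bear on them. Probe brightness is argued against, because 1000 draws of brightness-matched genes from elsewhere had medians no lower than -0.0711. A candidate explanation for these stretches is that the shRING1B and shGFP cells of A673 differ in DNA copy number. Going from 3 copies to 2 in every cell would give -0.585 in log2. The genes of this check had medians of -0.617, -0.564 and -0.405 on chromosomes 1, 7 and 8, against -0.182 on chromosome 2. Of the 17 runs, 12 had medians above -0.35, and the 264 genes of all 17 had -0.305. Most runs thus moved less than such a loss would give. All 619 tested genes between the run ends had -0.173. These include genes under the signal limit of the runs, where a fall would be hard to see. The sizes cannot decide about copy number, because a loss in part of the cells, or from a higher copy number, would give less. No DNA data were used here, and lower transcription over whole domains, which the hairpin might cause, was not tested and stays open.

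Zinc-finger genes between ZNF506 and ZNF254 on chromosome 19 were lower in A673 shRING1B. The changes spread more widely than in the lower runs (median absolute deviation 0.675 against 0.261, one-sided permutation p = 7e-05 over 100000 permutations). This cannot decide whether DNA copies were lost. The genes of the lower runs passed a higher limit on signal (5.78 against 4.06), and the zinc-finger stretch was picked by its values. The 20 nearest other genes had a median of 0.00152, which argues against a loss reaching over those genes. A loss confined to the zinc-finger genes stays open. Signal shared across the whole family is argued against by the median of -0.0398 among ZNF genes elsewhere that lie above the array median. Signal shared between near-identical members within the run cannot be told apart from a change of each gene, because sharing can be partial and no probe sequence was used. That RING1B depletion itself lowers these genes in A673 stays open as a hypothesis. In SK-ES1 the 8 of 29 above the median of all probe sets under shGFP had a median change of -0.293. None of the 8 was called by limma, and 2 were lower at an unadjusted p under 0.05. The 8 were kept by their level in the arrays that the change is measured from, which favours falls. Over all 29 the median in SK-ES1 was -0.133, while a fall of the genes at low signal would be hard to see.

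Interferon genes were lower in SK-ES1 shRING1B. A single SK-ES1 array as the source is argued against, because the camera adjusted p was at most 4.03e-14 when any of the 4 was left out. A response raised by the control hairpin, rather than one lowered by RING1B depletion, cannot be told apart, because no untreated cells were used here. The list's mean change in A673 under the same hairpins was -0.096, from a lower starting level, which decides neither way. An effect of RING1B on these genes in SK-ES1 may be one explanation and remains a hypothesis.

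The mean effect over both lines called 202 genes. Only 18 splits of the 8 arrays put 2 arrays of each line on each side, too few for a share under 0.05. Of these, 1, the real one, gave 202. The highest of the others gave 117 and is no chance split, since it sets the hairpins against each other with opposite sign in the lines and so equals the difference between lines, and the highest of the remaining 16 gave 76. Splits with 1 array of a line against 3 were not counted, because they change the group sizes within the lines. The 4 splits that keep the A673 arrays apart by hairpin and mix the SK-ES1 arrays gave 50 to 76 calls, and the 12 that mix the A673 arrays gave at most 2, so the arrays have a structure by A673 hairpin.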

How the results depend on the processing

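Cyclic loess and the fit without genes of the lower runs were chosen after the data were seen. No paired analysis was made, since the labels pair no arrays and replicate numbers follow accession order only, and the RNF2 alternatives were not run. Leaving out an array leaves 1 array in a group, which is assumed to vary like the others. No count changed direction of its majority, and the correlation between lines stayed between -0.0111 and 0.0835 with 1 array left out (0.0416 with all). Signal over background was not measured, and the cause of the shifts below was not tested except where fewer arrays or genes entered.

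Genes called in A673 (557) were 1052 with a trended, robust variance model, 213 in a fit of 4 arrays and 101 to 434 with 1 array left out. In SK-ES1 (10) they were 100 at an unadjusted p under 0.05 with 1.5-fold, 21 above the median signal, 16 with array medians set equal, 34 trended and robust, 4 with all probe sets tested, and 2 to 7 with 1 array left out. For the mean effect (202) they were 102 with 1.5-fold, 121 unadjusted with 1.5-fold, 337 above the median signal, 481 trended and robust, 8 in the additive model, 130 without genes of the lower runs, and 51 to 158 with 1 array left out. For the difference (117) they were 928 unadjusted with 1.5-fold, 179 above the median signal, 281 trended and robust, 60 with all probe sets, and 0 to 72 with 1 array left out. Between lines under shGFP (4572) they were 2790 with 1.5-fold, 2812 unadjusted with 1.5-fold, 7224 with all probe sets, and 3160 to 4674 with 1 array left out.

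List calls lost, as adjusted p, were these. With an estimated correlation they were developmental factors in A673 (0.565) and in the difference (0.291), DNA replication in A673 (0.565), SK-ES1 (0.748) and the mean (0.57), extracellular matrix in SK-ES1 (0.469), the difference (0.295) and between lines (0.469), interferon in the difference (0.0821), and repressed targets (0.469), mitosis (0.671) and ribosomal proteins (0.763) between lines. By fry they were DNA replication in A673 (0.186), SK-ES1 (0.513) and the mean (0.158), extracellular matrix in SK-ES1 (0.335) and the difference (0.147), and ribosomal proteins between lines (0.129). Developmental factors lost the call with quantile normalization repeated in A673 (0.104) and the difference (0.0536), and with cyclic loess (0.0535 and 0.0533).

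With 1 array left out, adjusted p ranged from 0.0199 to 0.0649 for developmental factors in A673, from 0.00125 to 0.202, 0.00458 to 0.374 and 9.62e-06 to 0.0125 for DNA replication in A673, SK-ES1 and the mean, and from 0.00724 to 0.407 and 0.00624 to 0.18 for extracellular matrix in SK-ES1 and the difference. It ranged from 4.21e-20 to 4.03e-14, 7.59e-10 to 2e-07 and 4.71e-07 to 6.92e-05 for interferon in SK-ES1, the mean and the difference, from 0.00997 to 0.0255 for developmental factors in the difference, and between lines from 2.66e-06 to 5.88e-05 for repressed targets, 5.46e-13 to 1.13e-11 for interferon, 0.00364 to 0.0169 for mitosis, 0.011 to 0.028 for extracellular matrix and 0.011 to 0.135 for ribosomal proteins. Ribosomal proteins in SK-ES1 (down, 0.89) ranged from 0.000951 to 0.925 and turned up without SK-ES1 shRING1B replicate 1 (0.00636). For named genes, the settings other than a left-out array gave 96 losses and 99 gains of a call among planned ones against 3559 without change, and left-out arrays gave 331 losses, 8 gains and 3549 without change, with 0 reversed.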

Other observations

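These runs were singled out after the data were seen. A stretch of chromosome 9 from KIF24 to FBXO10 moved the other way in A673. Its 22 genes had a median log2 change of 0.302 (shRING1B minus shGFP), with 0 of 22 below 0. Limma called 0 of them higher, and 13 were higher at an unadjusted p under 0.05. The medians were 0.287 and 0.348 in the A673 shRING1B replicates. In SK-ES1 the median was -0.031. On the X chromosome 3 runs were lower in A673, from CTPS2 to APOO, HDAC8 to TIMM8A and BCORL1 to STK26, with medians of -0.262, -0.273 and -0.371. Of their 13, 20 and 5 genes limma called 3, 3 and 0 lower, and 6, 9 and 3 were lower at an unadjusted p under 0.05. The check on alternate genes gave no held-out genes on the X chromosome, so these runs were not recovered there.

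Several lists had members that differed between the lines at baseline without a shift relative to other genes by camera. Of 27 HOX genes 9 were higher and 9 lower in SK-ES1, with HOXD9 at -2.27 (camera adjusted p = 0.935, fry adjusted p = 0.714). Of 24 EWSR1-FLI1 activated targets 5 were higher and 11 lower (mean -0.222, camera adjusted p = 0.253), with PAX7 at 2.12 and the neuropeptide NPY at -1.8. Of 14 neuronal genes 2 were higher and 8 lower, with NRCAM at -2.07 (mean -0.471, camera adjusted p = 0.121). By fry, which asks whether a list's genes move on balance one way, the activated targets (adjusted p = 0.000673) and the neuronal genes (0.00056) were lower in SK-ES1.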
